A study of Mus musculus with 48 samples.

How the data were processed

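PolyA RNA was sequenced from βTC3 and AJ-5257-1 cells plated in triplicate wells, 48 libraries in 16 groups of 3, in batches 1 and 2. Per the labels, RNA was extracted with Trizol and libraries were made from 500 ng of total RNA with a stranded mRNA kit. Per the submitters' processing notes, bcl2fastq 2.17, cutadapt 1.4.2, HISAT2, featureCounts 1.4.4 and edgeR were used with the mouse build mm10. The versions of HISAT2 and edgeR, the strand setting, the order of the steps and the annotation release are not given in the sources used here.

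The deposited per-sample tables hold counts, whole numbers of reads per Ensembl gene, 39017 identifiers in each of 48 libraries. The deposited count table of the series was checked against them and was equal in 48 of 48 columns. A further deposited table of normalized values, with 48 per-sample columns, was not used here, because how it was scaled is not stated. Symbols and positions were taken from GENCODE M21 (GRCm38), which named 37607 identifiers and left 1410 without a symbol. No replicate pair had identical values, and the chi-square per gene between replicates ran from 6.34 to 51.1, where pure sampling noise would give about 1. Total counts per library ran from 17.98 to 38.8 M, with a median of 26.1 M.

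Fits were made in R 4.3.3 with edgeR 4.0.16. The low-count filter was filterByExpr (minimum count 10, minimum total 15, minimum proportion 0.7), scaling was TMM, and the quasi-likelihood F test was used with Benjamini-Hochberg adjustment over the tested genes of each comparison at a threshold of 0.05. Libraries of 1 line and batch were fitted together, and comparisons across lines or batches were made in a fit of the 12 libraries of their groups. The SE of a log2 fold change was its size over the square root of F. CPM values use the TMM-scaled library sizes. The 19 comparisons were 7 of receptor or ligand against their controls, 1 of AJ cells with ALK7 against vector cells, 4 of dox alone, and 7 differences between effects. In counts simulated from the means, depths and dispersions of the data with known changes added, the fits found 22.4 to 76.1% of 1.5-fold changes, 56.7 to 89.6% of 2-fold changes and 87.9 to 100% of 4-fold changes, with 2 to 15 false calls. The changed genes were few and taken from those with higher counts, no other gene differed, and replicates were not paired. The number of false calls therefore does not carry over to comparisons where many genes pass.

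Gene lists, 30 in number with 522 genes of which 519 matched the annotation, were fixed before the data were examined, as were the groups, the comparisons, the tests, the alternatives and the rule for naming genes. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with p adjusted over all 187 tests of the 7 receptor and ligand comparisons, and within each comparison for the other 12. Of the 187, 51 passed, 27 upward and 24 downward, and 20 passed with an estimated correlation. With fry, which tests whether the genes of a list move one way on balance and compares them with no other genes, 112 passed. Counts of list members that rose or fell use the adjusted p over all tested genes, and those adjusted over the list alone use adjustment within the list.

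The rule for naming genes took, in the 7 receptor and ligand comparisons, Acvr1c, the 6 largest rises and 6 largest falls among genes past the threshold whose libraries did not overlap between groups, with a mean count of at least 20 in the higher group and a symbol that was not a predicted or clone name, up to 4 members of each list with the smallest adjusted p, and, whether past the threshold or not, Smad7, Skil, Pmepa1, Cdkn1a, Cdkn2b, Bcl2l11, Inhbb, Ins1, Ins2, Pdx1 and Mki67. In the other comparisons it took 3 rises, 3 falls and up to 2 members of each list. Some genes the rule took are not reported here. Genes singled out otherwise are said to be so. A fold against a group at 0 was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval.

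Whether replicate numbers pair libraries across groups was tested before fits were compared, on residuals of genes with a mean log2 CPM over 4 (8835 genes). Pairs of groups counted as paired where each replicate's correlation across genes exceeded 0.1. This held for 10 of 10 pairs of groups in βTC3 batch 1 (r from 0.146 to 0.813), for the 1 pair in βTC3 batch 2 (0.106 to 0.417), for 5 of 10 in AJ batch 1 and for 2 of 6 in AJ batch 2. βTC3 was therefore read as paired and AJ not, and values with the replicate number as a block are printed beside βTC3 results where they move a count by over 1.5 times or change a call. Over all genes with a mean log2 CPM over 0 (13248 genes), 8 of 10, 0 of 1, 4 of 10 and 0 of 6 pairs of groups passed, so that the pairing rests on the more abundant genes.

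Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, a stricter filter (1 CPM in 3 libraries), an absolute log2 fold change of at least 1, the replicate block, a fit of the compared groups alone and each library left out in turn. Calls were also tested against other splits of the same libraries, 10 for 3 against 3, 25 for a difference of effects and 100 for shared calls, with a fixed seed of 7. Vector cells at 24 h of dox are the control of ALK7-CA at 24 h and also a group of the dox comparison, so no overlap or correlation between these comparisons was computed.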

Results

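The series held strand-specific polyA RNA sequencing of 48 libraries from a pair of mouse pancreatic neuroendocrine tumour (PanNET) cell lines, the insulinoma line βTC3 and AJ-5257-1 (AJ below). The question stated for it was which genes respond to ALK7, the activin receptor-like kinase encoded by Acvr1c. Cells carried a doxycycline (dox) inducible plasmid that was empty (vector) or encoded constitutively active ALK7 (ALK7-CA) or, in AJ, the wild-type receptor (ALK7), and some cultures received the ligand activin B at 50 ng/ml for 24 h. Batch 1 held, in each line, vector cells after 0, 2 and 24 h of dox at 2 µg/ml and ALK7-CA cells after 2 and 24 h. Batch 2 held vector cells without dox, untreated or given activin B, in both lines, and AJ cells with ALK7 after 24 h of dox with and without activin B. Each of the 16 groups had 3 libraries, which differed from one another by more than sampling noise. Nothing in the labels says that they came from separate cultures beyond being plated in triplicate, so p-values measure the spread between these samples. Total counts ran from 17.98 to 38.8 M per library (median 26.1 M), 22.1 to 38.8 M in batch 1 and 17.98 to 25.3 M in batch 2. Below, values are CPM (counts relative to the scaled library size) as mean ± SD with n = 3 libraries per group, changes are log2 fold changes with their standard error (SE), and a gene rose or fell where the adjusted p of edgeR was under 0.05.

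Acvr1c (ENSMUSG00000026834, GRCm38 chromosome 2, 58267453 to 58357895, minus strand), the gene of the receptor itself, did not rise in any group with a receptor plasmid, so its count does not check the labels. In βTC3 it stood at 139 ± 16.6 CPM in vector cells at 0 h, 130.1 ± 12.3 at 2 h and 122 ± 11.1 at 24 h, against 117 ± 13.5 with ALK7-CA at 2 h, which did not pass (log2 change −0.15, adjusted p = 0.755, though it did with the replicate number as a block), and 76.7 ± 8.33 at 24 h, a fall (log2 change −0.66, SE 0.115, adjusted p = 0.00122). In AJ it stood at 10.3 ± 0.714, 9.61 ± 0.582 and 10.6 ± 0.966 CPM in vector cells at 0, 2 and 24 h, and fell with ALK7-CA to 4.42 ± 0.740 at 2 h and 3.80 ± 2.05 at 24 h (adjusted p = 0.00816 and 0.00042). Replicate 1 at 24 h, where transcripts of βTC3 were read (values below), enters this SD. Activin B lowered it from 10.47 ± 0.337 to 3.61 ± 0.403 in AJ vector cells and from 12.4 ± 1.80 to 3.67 ± 0.333 in AJ cells with ALK7 (adjusted p = 4.97e-06 and 8.89e-07), and from 132 ± 8.78 to 110.4 ± 8.71 in βTC3 (adjusted p = 0.0329). This last call ended without replicate 1 or 2 of the untreated group or replicate 1 or 3 of the treated group, with log2 changes of −0.24, −0.22, −0.29 and −0.19. AJ cells with ALK7 and no ligand did not pass against vector cells (log2 difference 0.25, adjusted p = 0.16), except without replicate 3 of the ALK7 group (0.37). Inhbb, which encodes the subunit of activin B, did not pass the filter on low counts in any of these 7 comparisons, so it was not tested.

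Constitutively active ALK7 was first compared with vector after 24 h of dox in βTC3. Several feedback genes of the SMAD2/3 pathway rose. Pmepa1 and Ldlrad4, membrane proteins that restrain TGF-β signalling, rose 10.4-fold (147 ± 17.5 against 14.2 ± 1.197 CPM) and 4.94-fold (24.2 ± 2.86 against 4.89 ± 0.305 CPM). Smad7, the inhibitory SMAD, rose 2.92-fold (24.3 ± 0.558 against 8.33 ± 0.339 CPM), Skil, a SMAD corepressor, 3.16-fold (124 ± 13.3 against 39.2 ± 3.66 CPM), and Bambi, a decoy receptor, 2.52-fold. The transcription factor gene Sox4 rose 4.43-fold (149.6 ± 7.77 against 33.8 ± 0.518 CPM). Of the measured members of the SMAD2/3 target and feedback list, 12 rose, 2 fell and 9 did not pass (14 and 3 adjusted over the list alone, adjusted p = 5.17e-23, and adjusted p = 0.00373 with an estimated correlation). Bmf, which encodes a BH3-only activator of apoptosis, rose 15.2-fold (34.5 ± 0.268 against 2.27 ± 0.236 CPM), with log2 change 3.92, SE 0.129 and adjusted p = 2.6e-10. Vector libraries had read Bmf at 4.60, 4.25 and 3.25 CPM at 0 h of dox and 4.37, 4.45 and 4.23 at 2 h. The difference at 24 h thus includes a lower control. Dapk1 and Bcl2l11 (Bim) rose 1.56-fold and 1.24-fold, while Pmaip1 (Noxa) fell 3.58-fold (0.693 ± 0.266 against 2.49 ± 0.677 CPM). In the pro-apoptotic list 5 rose, 1 fell and 15 did not pass (5 and 1 adjusted over the list alone, adjusted p = 0.0224, and adjusted p = 0.0843 with an estimated correlation).

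The largest rises in βTC3 at 24 h by the naming rule were in Cyp4f39, at 59.5-fold (16.1 to 498) by its counting interval, Mybpc1 at 44.9-fold, Prr5l, whose product binds mTOR complex 2, at 41.9-fold (17.0 ± 0.417 against 0.404 ± 0.0830 CPM), Chad at 34.3-fold (11.4 to 169.6) by its counting interval, Jam2, a junctional adhesion molecule, at 29.7-fold (131 ± 8.71 against 4.41 ± 0.594 CPM), and Adamts7 at 28.8-fold. Intervals and floors cover counting error only, and a floor is 3 counts over the group. Nppa, the precursor of atrial natriuretic peptide, was at 0 in the ALK7-CA libraries and 1.53 ± 0.353 CPM in vector, at least 40.5-fold lower. Vector cells themselves had held 1 count at 0 h of dox, so this is mainly a rise of the control. Trim17 fell 3.85-fold. Among islet genes, Pax4, a transcription factor of beta and delta cell formation, rose 6.03-fold (68.4 ± 2.89 against 11.3 ± 0.890 CPM) and Glp1r, the GLP-1 receptor, 1.55-fold, whereas glucagon (Gcg) fell 1.44-fold (87.0 ± 2.56 against 125 ± 5.30 CPM). Ins1 and Ins2 did not pass (log2 change −0.26 and −0.27, adjusted p = 0.229 and 0.341). Krt7, an epithelial keratin, rose 3.70-fold (32.8 ± 1.29 against 8.86 ± 0.420 CPM) and S100a4 8.90-fold. The BMP antagonist Grem1 rose 5.10-fold and the BMP target Id1 fell 1.68-fold. Several endoplasmic reticulum chaperones fell, among them Pdia6 (1.45-fold), Hyou1 (1.32-fold), Calr (1.26-fold) and Sdf2l1 (1.55-fold). In that list none rose, 10 fell and 9 did not pass (0 and 11 adjusted over the list alone, adjusted p = 3.29e-06, and adjusted p = 0.145 with an estimated correlation). Several interferon response genes fell too, with Ddx58 lower by 1.43-fold, Isg15 by 1.65-fold and Bst2 by 1.68-fold. In the list none rose, 10 fell and 12 did not pass (1 and 14 adjusted over the list alone, adjusted p = 1.99e-05, and adjusted p = 0.0221 with an estimated correlation). Vector cells had themselves changed with 24 h of dox, opposite to the ALK7-CA difference and by at least 0.5 times its size (a bound set after the results were seen), for Grem1 (log2 change −1.96), Gcg (0.53), Pmaip1 (1.15), Calr (0.28), Hyou1 (0.52), Pdia6 (0.52) and Sdf2l1 (0.51). These differences include that change of the control. The proliferation marker Mki67 did not pass (log2 change −0.01, adjusted p = 0.98), nor did Cdkn2b (p15) at 0.31, adjusted p = 0.0675. In all, 2134 of 15801 genes passed, 1268 up and 866 down, 503 of them by 2-fold or more. The libraries of the groups did not overlap for 30.2% of tested genes, where chance gives 10% if libraries are not paired. For dox at 2 h against 0 h in βTC3 vector cells, where 1 gene passed, this share was 5.61%. With the replicate number as a block, 4410 genes passed for ALK7-CA at 24 h, and Cdkn2b, Ins1 and Ins2 passed as well. Cdkn2b also passed without replicate 2 of the vector group (0.39).

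**Figure D1:**
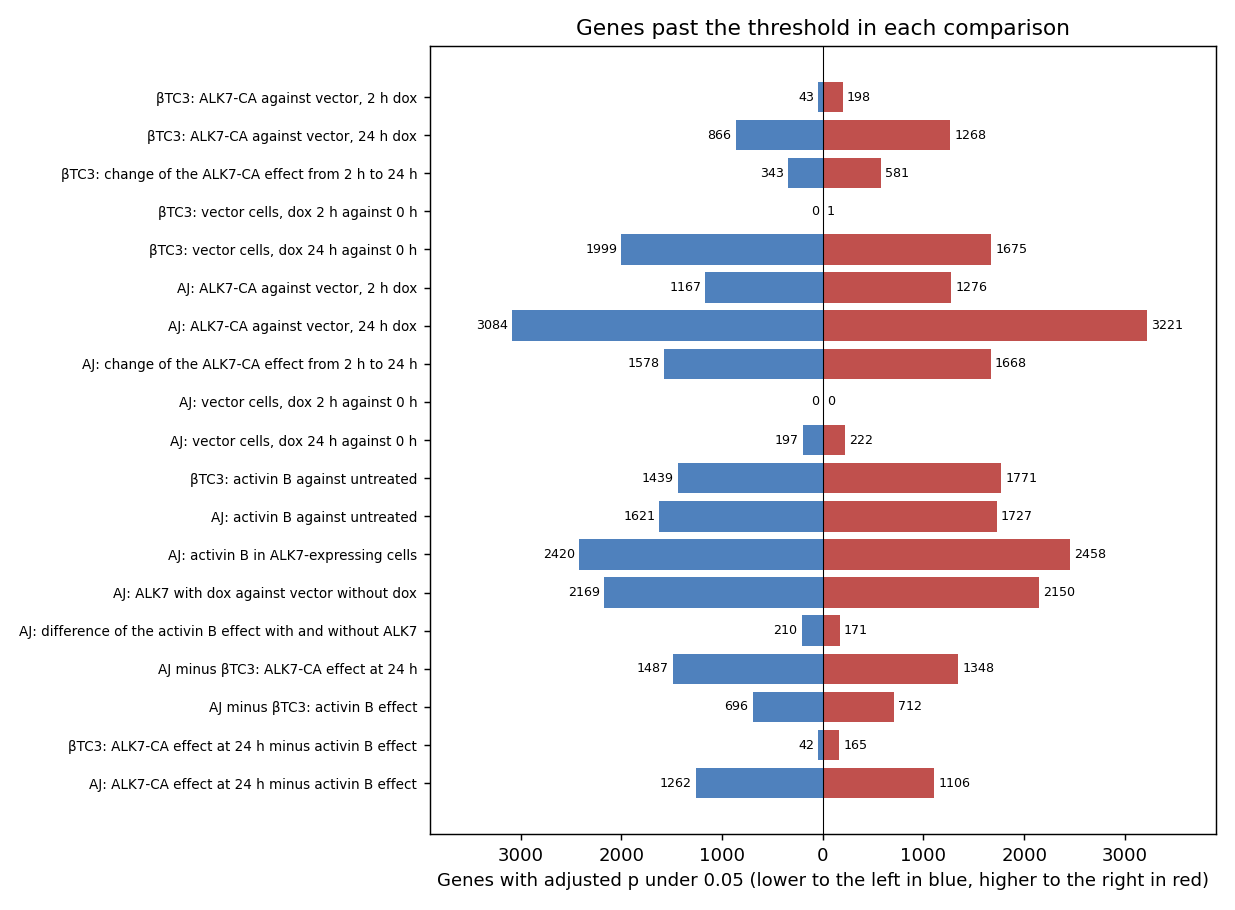
Genes with an adjusted p under 0.05 in each of the 19 comparisons. Bars to the right (red) count genes that were higher and bars to the left (blue) genes that were lower, on an axis in numbers of genes; the longest are those of AJ with ALK7-CA at 24 h (3221 up, 3084 down).

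In AJ cells, ALK7-CA at 24 h raised several feedback genes of the pathway as well. Ldlrad4 rose 144-fold (85.4 ± 9.12 against 0.588 ± 0.109 CPM), Sox4 60.8-fold (403 ± 25.7 against 6.62 ± 0.933 CPM), Pmepa1 13.96-fold (161 ± 10.3 against 11.5 ± 1.89 CPM), Smad7 10.6-fold (101 ± 5.34 against 9.48 ± 1.03 CPM) and Skil 3.73-fold (160.3 ± 5.96 against 42.9 ± 4.31 CPM). Fst, whose product follistatin binds activins, had 3 counts in the vector group and 63.3 ± 4.02 CPM with ALK7-CA, 1902-fold (650.4 to 9225) higher by its counting interval. In AJ vector cells Fst stood at 0.211 CPM with activin B and 0.242 without it. In βTC3 at 24 h it stood at 0.0244 CPM with ALK7-CA and 0.0219 in vector cells. Of the SMAD2/3 list 19 rose, 1 fell and 4 did not pass, or 19 and 1 adjusted over the list alone (adjusted p = 3.24e-37, and adjusted p = 0.000206 with an estimated correlation). Bmf rose 19.0-fold (73.4 ± 2.06 against 3.86 ± 0.126 CPM), Hrk, also a BH3-only gene, 2.14-fold and Bcl2l11 1.37-fold, and the anti-apoptotic gene Bcl2 fell 1.67-fold (28.0 ± 2.79 against 46.7 ± 1.86 CPM). The pro-apoptotic list itself did not pass (adjusted p = 0.318). Cdkn2b rose 3.07-fold (11.1 ± 1.30 against 3.61 ± 0.580 CPM) and Cdkn1a (p21) 1.35-fold. Some mitotic genes fell by less, with Cenpa lower by 1.34-fold, Kif20a by 1.32-fold and Ccnb2 by 1.24-fold. In the G2/M list none rose, 14 fell and 10 did not pass (0 and 20 adjusted over the list alone, adjusted p = 0.00201, and adjusted p = 0.368 with an estimated correlation). Mki67 did not pass (log2 change −0.18, adjusted p = 0.0672), though it did without replicate 2 of the vector group (−0.25).

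Several genes of the endocrine cell fell in AJ at 24 h. Glis3, a beta cell transcription factor, fell 4.43-fold (2.40 ± 0.244 against 10.6 ± 0.251 CPM), Abcc8, the sulfonylurea receptor, 3.17-fold (107 ± 13.4 against 338 ± 31.3 CPM), Foxa2 2.09-fold, Rfx6 1.84-fold and Pdx1 1.48-fold. In the beta cell list 6 rose, 13 fell and 8 did not pass, or 6 and 13 adjusted over the list alone (adjusted p = 0.00411, and adjusted p = 0.5 with an estimated correlation). The median of that list was −0.55 and its mean 0.17, of the opposite sign to the median and to the test. Replicate 1, with its transcripts of βTC3, enters these values. Without it 3 rose, 17 fell and 7 did not pass, with a mean of −0.77 (adjusted p = 3.72e-06, and adjusted p = 0.07 with an estimated correlation). Ins1 read 172, 1.27 and 0.922 CPM and Ins2 626, 0.0726 and 0.137 CPM (by total count) in replicates 1, 2 and 3 of the ALK7-CA group, and their calls ended without replicate 1, where Ins2 stood at −1.95 on the log2 scale. The call of Ins2 (log2 change 8.92) also ended without replicate 1 of the vector group (8.56), and that of Ins1 in a fit of these 2 groups alone (5.76). Several vesicle genes fell, among them Ptprn2 (2.08-fold), Scg2 (2.40-fold) and Chgb (1.57-fold). In that list 2 rose, 9 fell and 9 did not pass (2 and 9 adjusted over the list alone, adjusted p = 0.00424, and adjusted p = 0.045 with an estimated correlation). Without replicate 1 of the ALK7-CA group 1 rose, 8 fell and 11 did not pass (adjusted p = 0.00165). The list then no longer passed with an estimated correlation (adjusted p = 0.0647). Ppy and Pyy, peptide genes of the islet PP cell, rose 57.3-fold and 26.8-fold, while somatostatin (Sst) fell 4.70-fold. Ttr fell 5.24-fold (67.3 ± 10.2 against 352 ± 10.4 CPM) and Nefl 5.01-fold, and the neuronal tubulin Tubb3 rose 3.99-fold (432 ± 29.0 against 108 ± 23.9 CPM). Some immediate early genes rose, with Egr1 higher by 5.97-fold, Fos by 4.34-fold and Dusp1 by 2.58-fold. In the list 13 rose, 1 fell and 4 did not pass (13 and 2 adjusted over the list alone, adjusted p = 1.23e-06, and adjusted p = 0.0989 with an estimated correlation). The matrix genes Timp3 and Mmp2 rose 8.38-fold (32.4 ± 1.99 against 3.86 ± 0.537 CPM) and 3.59-fold, while in the mesenchymal and matrix list 6 rose, 5 fell and 6 did not pass (7 and 5 adjusted over the list alone, adjusted p = 0.0481, and adjusted p = 0.129 with an estimated correlation). In the glycolysis and hypoxia list 1 rose, 12 fell and 6 did not pass (1 and 14 adjusted over the list alone, adjusted p = 0.0063, and adjusted p = 0.368 with an estimated correlation), Ndrg1 falling 2.71-fold and Vegfa 1.75-fold while the collagen prolyl hydroxylase P4ha2 rose 5.74-fold. The largest rises besides Fst were in Angptl2 at 869-fold (240.1 to 7181), Bdkrb2 at 866-fold (155 to 34233) and Tmem91 at 429-fold (146 to 2082), each by its counting interval, and in Spink12, which was at 0 in vector cells and at least 71.4-fold higher. Slc22a22 was 198-fold (35.2 to 7860.5) lower by its counting interval, and Brinp3 was 38.99-fold (0.119 ± 0.108 against 4.97 ± 1.19 CPM) lower. Vector cells had themselves risen from 0.332 ± 0.107 CPM at 0 h, so most of this is a change of the control. Altogether 6305 of 15487 genes passed, 3221 up and 3084 down, 1715 of them by 2-fold or more. The libraries of the groups did not overlap for 47.8% of tested genes, where chance gives 10%. In replicate 1 of this group, 19 genes typical of βTC3, Npy among them, read a median of 6.35% of their βTC3 level, and without that library 5794 genes passed.

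**Figure D2:**
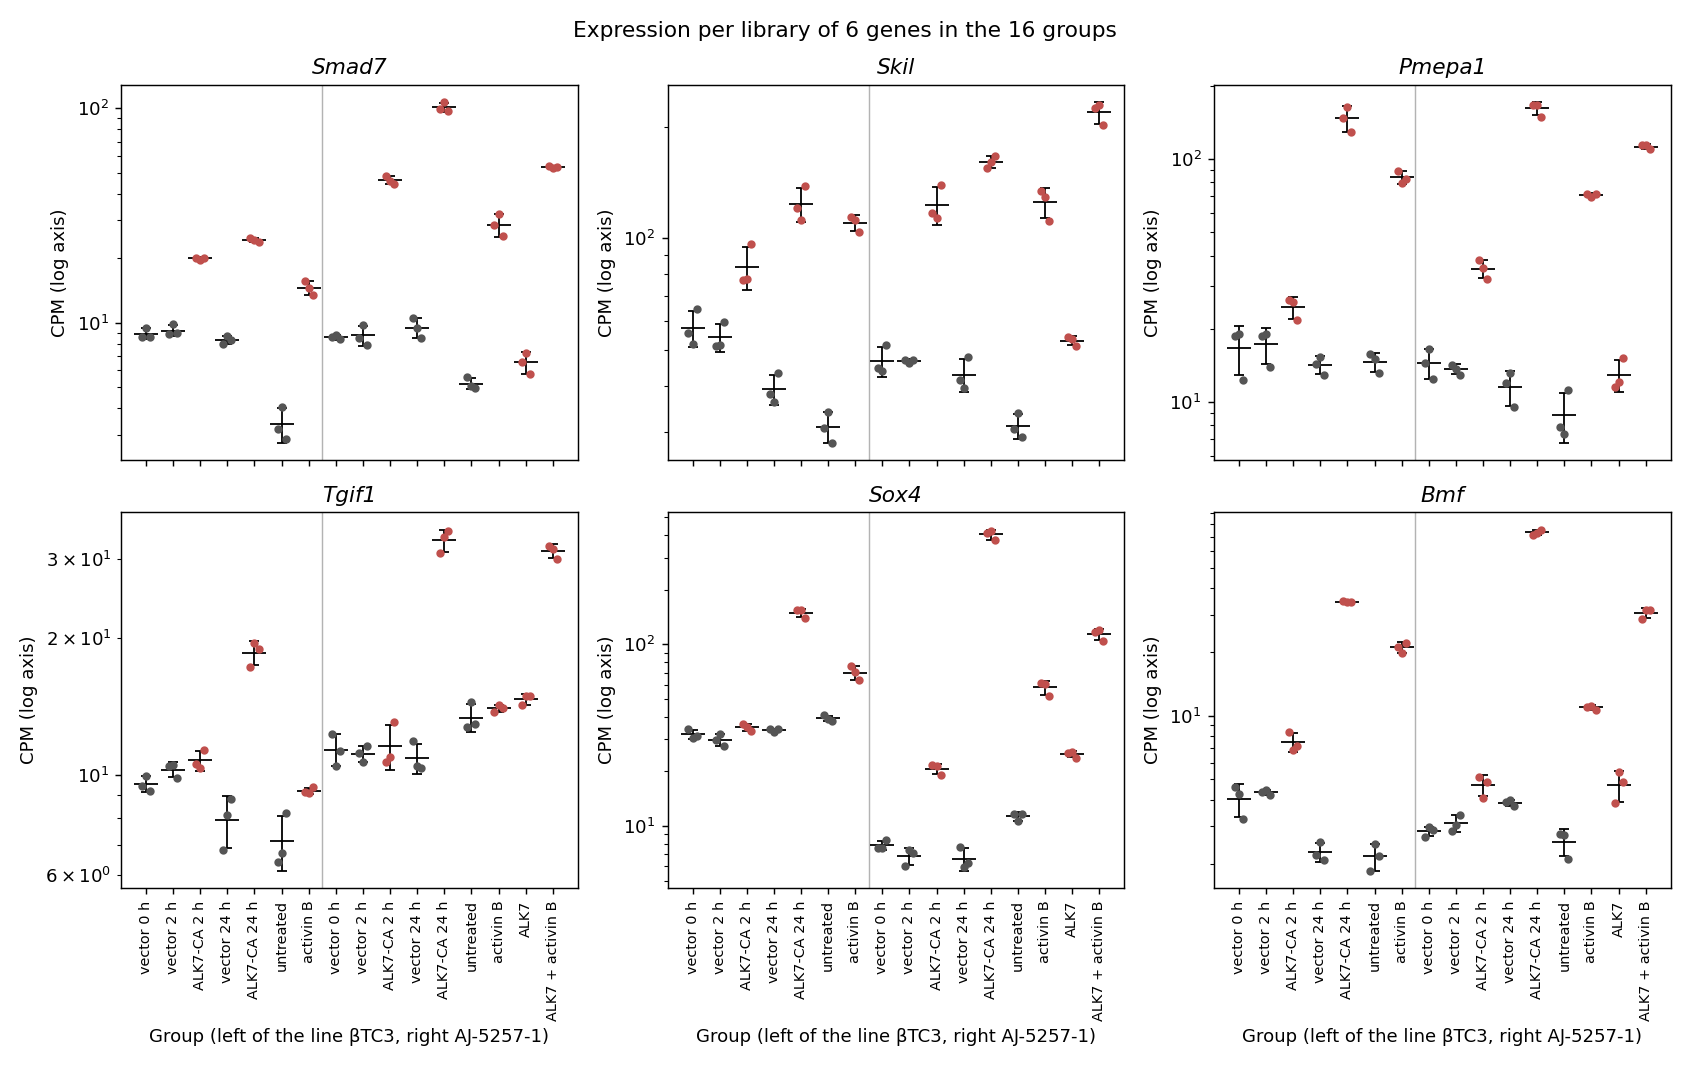
CPM per library (points, log axis) of Smad7, Skil, Pmepa1, Tgif1, Sox4 and Bmf in the 16 groups, with the group mean (bar) and SD (whiskers), n = 3. Red points are groups with ALK7-CA, ALK7 or activin B and grey points vector cells without ligand; Sox4 in AJ stands at 403 ± 25.7 CPM with ALK7-CA at 24 h and 6.62 ± 0.933 in vector cells.

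After 2 h of dox, few of these genes differed in βTC3. Smad7 was 2.171-fold (19.96 ± 0.242 against 9.19 ± 0.558 CPM) higher (log2 change 1.12, SE 0.0685, adjusted p = 6.32e-06) and Btg2, an antiproliferative gene, 1.56-fold higher. Myom1 was higher by 5.16-fold (7.13 ± 0.553 against 1.38 ± 0.166 CPM), Efna5 by 3.28-fold and the Y-linked helicase gene Ddx3y by 3.06-fold. Bmf was 1.73-fold (7.51 ± 0.788 against 4.35 ± 0.111 CPM) higher and Prr5l 3.39-fold higher, and Tff3 lower by 1.57-fold, calls lost in a fit of these 2 groups alone (adjusted p = 0.00477, 0.000726 and 0.00552 in the fit of all groups). Pmepa1 did not pass (log2 change 0.51, adjusted p = 0.204) but did with the replicate block. In the SMAD2/3 list 5 rose, none fell and 18 did not pass, or 7 and 1 adjusted over the list alone (adjusted p = 9.33e-07, and adjusted p = 0.061 with an estimated correlation). In the interferon list none rose, 3 fell and 19 did not pass, or 0 and 5 adjusted over the list alone (adjusted p = 5.88e-08, and adjusted p = 0.00696 with an estimated correlation). In the chaperone list none rose, none fell and 19 did not pass, or 5 and 0 adjusted over the list alone (adjusted p = 1.23e-06, and adjusted p = 0.129 with an estimated correlation), with a direction opposite to that at 24 h. Of 15801 genes, 241 passed, 198 up and 43 down, and with the replicate block 1136, of which 63.6% were up against 82.2% without it. The block also brought the anti-apoptotic, G1/S, vesicle, integrated stress response and oxidative phosphorylation lists past the threshold (adjusted p = 0.0355, 0.0441, 0.0142, 0.0318 and 0.0161). This was at the preset correlation, and an estimated one was not used with the block. The count was 93 and 123 without replicates 1 and 2 of the ALK7-CA group and 158, 77 and 136 without replicates 1, 2 and 3 of the vector group, and 31 in the fit of these 2 groups alone. It was 365 with DESeq2 and 150 without the filter on low counts.

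In AJ the 2 h comparison already held many differences. Smad7 was 5.29-fold (46.2 ± 2.02 against 8.73 ± 0.957 CPM) higher, Sox4 3.02-fold (20.7 ± 1.37 against 6.82 ± 0.724 CPM), Skil 2.63-fold, Pmepa1 2.59-fold (35.3 ± 3.10 against 13.6 ± 0.640 CPM) and Bcl2l11 1.48-fold, while Bmf was 1.51-fold (4.69 ± 0.539 against 3.10 ± 0.279 CPM) higher. Of the SMAD2/3 list 11 rose, 1 fell and 12 did not pass, or 14 and 1 adjusted over the list alone (adjusted p = 2.83e-17, and adjusted p = 0.00416 with an estimated correlation). Of the BMP target list 7 rose, 2 fell and 2 did not pass, or 7 and 2 adjusted over the list alone (adjusted p = 7.73e-08, and adjusted p = 0.0475 with an estimated correlation), with Dlx3, Atoh8 and Id2 higher by 6.02-fold, 3.30-fold and 1.60-fold. Cftr, the chloride channel of duct cells, was 41.5-fold (15.01 ± 2.45 against 0.355 ± 0.104 CPM) higher, the sodium channel gene Scn1a 6.93-fold and Hes1, a Notch target, 3.59-fold. Glis3 was lower by 4.10-fold (2.73 ± 0.156 against 11.2 ± 0.837 CPM), Ttr by 3.33-fold (133 ± 2.74 against 442 ± 13.2 CPM) and Foxf2 by 19.6-fold, and Slc22a22 was at 0, at least 84.2-fold lower. The duct list held 1 gene that rose and 4 that did not pass (2 and 0 adjusted over the list alone, adjusted p = 0.000917, and adjusted p = 0.0393 with an estimated correlation), and in the hepatocyte list, led by Ttr and Serpina1a, none rose, 2 fell and 2 did not pass, or 0 and 2 adjusted over the list alone (adjusted p = 1.02e-07, and adjusted p = 0.00423 with an estimated correlation). In the interferon list none rose, 5 fell and 13 did not pass (0 and 5 adjusted over the list alone, adjusted p = 0.00411, and adjusted p = 0.191 with an estimated correlation), Psmb8 of the immunoproteasome being 2.60-fold lower. Some cholesterol synthesis genes were higher, Dhcr7 by 1.28-fold and Hmgcs1 by 1.25-fold. In that list 7 rose, none fell and 14 did not pass (9 and 0 adjusted over the list alone, adjusted p = 0.00316, and adjusted p = 0.112 with an estimated correlation). 2443 of 15487 genes passed, 1276 up and 1167 down, 558 by 2-fold or more. ALK7-CA cells at 0 h were not analysed here, so a difference at 2 h includes any that the cell populations had before dox. Y-linked transcripts, singled out after their values were seen, were higher with ALK7-CA in each of 14 combinations of gene, line and time tested, by 1.64 to 3.29-fold.

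The change of the ALK7-CA effect from 2 to 24 h was tested as an interaction. In AJ the effect on Ldlrad4 grew by 5.72 on the log2 scale (SE 0.224, adjusted p = 2.72e-09), on Sox4 by 4.33 and on Bmf by 3.65, and the effects on Abcc8, Id2 and Smad3 moved by −1.89, −1.12 and −1.22. In βTC3 the effect on Bmf grew by 3.13 (SE 0.172, adjusted p = 1.51e-07), on Pmepa1 by 2.87, on Pax4 by 2.48, on Sox4 by 1.91 and on Krt7 by 1.81, while those on Pdyn, Gcg and Pdia6, which rose in the vector control, moved by −1.85, −0.94 and −0.76. The lower level of Bmf in the βTC3 vector control at 24 h enters its value. In the SMAD2/3 list of AJ 16 rose, 2 fell and 6 did not pass (18 and 2 adjusted over the list alone, adjusted p = 4.71e-16, and adjusted p = 0.00255 with an estimated correlation). In that of βTC3 10 rose, 1 fell and 12 did not pass (11 and 1 adjusted over the list alone, adjusted p = 3.94e-15, and adjusted p = 0.0113 with an estimated correlation). The change passed for 3246 genes in AJ (1668 up, 1578 down) and 924 in βTC3 (581 up, 343 down), the latter 2553 with the replicate block. Called at both times in the same direction were 1594 AJ genes (816 up, 778 down, where independent lists would share 265 and 232; r = 0.39 and rho = 0.40 across genes) and 153 βTC3 genes (123 up, 30 down, against 15.9 and 2.36; r = 0.18 and rho = 0.21, 538 shared with the block). Genes are not independent replicates, here and for every correlation across genes below. In the opposite direction were 221 and 13. Some genes named at 24 h differed in the same direction at 2 h with no called change between the times, so differences that preceded dox may enter their values at 24 h. They were Acvr1c, Atoh8, Bcl2l11, Glis3, Psmb8, Serpina1e and Slc22a22 in AJ and Ddx58, Isg15 and Myom1 in βTC3. Genes called as changing between the times may hold such differences too. Ttr in AJ, for one, was at −1.74 on the log2 scale at 2 h and its effect moved by −0.65 to 24 h.

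Activin B was compared with no ligand in vector cells. In βTC3, Pmepa1 rose 5.74-fold (83.8 ± 5.11 against 14.6 ± 1.32 CPM), Skil 3.54-fold (110.0 ± 5.34 against 31.1 ± 2.99 CPM), Smad7 4.33-fold, Ldlrad4 3.64-fold and Bambi 3.06-fold. Among SMAD2/3 list members 14 rose, 2 fell and 6 did not pass, or 15 and 3 adjusted over the list alone (adjusted p = 2.07e-17, and adjusted p = 0.0104 with an estimated correlation). Prr5l rose 60.0-fold (19.4 ± 1.08 against 0.325 ± 0.115 CPM), Jam2 13.8-fold, Tph1, the first enzyme of serotonin synthesis, 15.1-fold (12.6 ± 0.410 against 0.838 ± 0.0988 CPM) and Igfbpl1 12.3-fold, and Ros1, Gbx2 and Wfdc16 fell 9.41-fold, 5.34-fold and 4.66-fold. Bmf rose 9.72-fold (20.99 ± 1.18 against 2.168 ± 0.315 CPM) and Trp53inp1 2.11-fold. In the pro-apoptotic list 5 rose, 1 fell and 12 did not pass (5 and 1 adjusted over the list alone, adjusted p = 0.0178, and adjusted p = 0.217 with an estimated correlation). Pax4 rose 5.21-fold (108 ± 1.11 against 20.8 ± 0.767 CPM), while Ins2 fell 1.397-fold, Ins1 1.29-fold, Pdx1 1.41-fold, Pcsk1, the prohormone convertase, 1.61-fold and Gcg 3.51-fold (31.1 ± 4.65 against 109 ± 3.86 CPM). In the non-beta islet list 1 rose, 3 fell and 3 did not pass (1 and 3 adjusted over the list alone, adjusted p = 0.0061, and adjusted p = 0.145 with an estimated correlation), Ppy rising 14.6-fold. The chaperone Hspa5 (BiP) fell 1.55-fold, Pdia6 1.91-fold and Sdf2l1 2.06-fold. In the chaperone list none rose, 17 fell and 2 did not pass, or 0 and 18 adjusted over the list alone (adjusted p = 1.18e-20, and adjusted p = 0.00854 with an estimated correlation). In the integrated stress response list 2 rose, 9 fell and 8 did not pass (2 and 9 adjusted over the list alone, adjusted p = 0.033, and adjusted p = 0.3 with an estimated correlation), Asns falling 1.29-fold. Mki67 did not pass (log2 change 0.00, adjusted p = 0.996). 3210 of 14429 genes passed, 1771 up and 1439 down, 405 by 2-fold or more.

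In AJ vector cells activin B raised Fam210b 21.9-fold (159.6 ± 4.17 against 7.27 ± 1.04 CPM), Tmod1, a pointed-end capping protein of actin, 35.2-fold (47.6 ± 2.1699 against 1.35 ± 0.116 CPM), Ldlrad4 45.9-fold, Pmepa1 8.09-fold (71.0 ± 1.04 against 8.80 ± 2.04 CPM), Smad7 5.50-fold, Sox4 5.13-fold (58.1 ± 5.06 against 11.3 ± 0.580 CPM) and Skil 4.01-fold, and Tmem91, at 0 in untreated cells, at least 72.2-fold. Bmf rose 4.30-fold (10.9 ± 0.274 against 2.53 ± 0.369 CPM). Cd44 fell 7.84-fold and Cd36 7.74-fold. Of the SMAD2/3 list 12 rose, none fell and 9 did not pass, or 12 and 0 adjusted over the list alone (adjusted p = 1.69e-27, and adjusted p = 0.000206 with an estimated correlation). In the BMP list 4 rose, none fell and 5 did not pass, or 4 and 0 adjusted over the list alone (adjusted p = 0.000267, and adjusted p = 0.0843 with an estimated correlation), with Smad6 and Smad9 up 11.03-fold and 1.94-fold. Several targets of p53 rose, among them Btg2 (2.40-fold), Ccng1 (1.36-fold) and Cdkn1a (1.42-fold). In that list 9 rose, none fell and 8 did not pass, or 10 and 0 adjusted over the list alone (adjusted p = 6.3e-07, and adjusted p = 0.00787 with an estimated correlation). Some cell cycle genes fell by small amounts, Mki67 by 1.18-fold, Bub1 by 1.28-fold and Rrm2 by 1.29-fold. In the G2/M list none rose, 19 fell and 5 did not pass (0 and 21 adjusted over the list alone, adjusted p = 2.33e-08, and adjusted p = 0.0836 with an estimated correlation). In the G1/S list none rose, 15 fell and 7 did not pass (0 and 16 adjusted over the list alone, adjusted p = 9.1e-06, and adjusted p = 0.0989 with an estimated correlation). Of the beta cell list 4 rose, 10 fell and 14 did not pass, or 5 and 10 adjusted over the list alone (adjusted p = 0.00195, and adjusted p = 0.0429 with an estimated correlation), with Abcc8 down 2.25-fold (124 ± 2.21 against 280.2 ± 3.90 CPM), Pcsk1 down 2.15-fold and Pax4 up 3.31-fold. Gcg, the glucagon gene of the alpha cell, fell 2.99-fold. In the cholesterol list none rose, 10 fell and 11 did not pass (1 and 11 adjusted over the list alone, adjusted p = 0.00176, and adjusted p = 0.0843 with an estimated correlation). 3348 of 14872 genes passed, 1727 up and 1621 down, 443 by 2-fold or more.

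In AJ cells with the ALK7 plasmid and dox, activin B raised Smad7 8.16-fold (53.3 ± 0.692 against 6.53 ± 0.744 CPM), Ldlrad4 101-fold (37.9 ± 2.96 against 0.366 ± 0.124 CPM), Pmepa1 8.69-fold (112 ± 2.41 against 12.9 ± 1.98 CPM), Sox4 4.56-fold, Skil 4.11-fold and Bmf 6.53-fold (30.6 ± 1.72 against 4.70 ± 0.790 CPM). Cdkn2b rose 2.55-fold (9.63 ± 0.711 against 3.78 ± 0.788 CPM). Tmem91 was 871-fold (156 to 34447) higher by its counting interval, and Angptl2, at 0 without ligand, at least 44.7-fold higher. Bmp7 fell 25.6-fold (0.499 ± 0.138 against 13 ± 0.463 CPM) and Slc2a2, the GLUT2 glucose transporter, 12.9-fold (0.0761 ± 0.0735 against 1.07 ± 0.240 CPM). Among SMAD2/3 list members 16 rose, none fell and 5 did not pass, or 17 and 0 adjusted over the list alone (adjusted p = 3.35e-34, and adjusted p = 0.000138 with an estimated correlation), in the BMP list 7 rose, 1 fell and 1 did not pass, or 7 and 1 adjusted over the list alone (adjusted p = 5.13e-07, and adjusted p = 0.0429 with an estimated correlation). In the p53 list 8 rose, 1 fell and 8 did not pass (8 and 1 adjusted over the list alone, adjusted p = 0.00313, and adjusted p = 0.0529 with an estimated correlation). In the G2/M list none rose, 23 fell and 1 did not pass, or 0 and 23 adjusted over the list alone (adjusted p = 4.8e-12, and adjusted p = 0.0442 with an estimated correlation), Mki67 being 1.26-fold lower. In the G1/S list none rose, 18 fell and 4 did not pass, or 0 and 19 adjusted over the list alone (adjusted p = 1.8e-08, and adjusted p = 0.0449 with an estimated correlation). In the beta cell list 3 rose, 15 fell and 10 did not pass, or 3 and 15 adjusted over the list alone (adjusted p = 2.33e-08, and adjusted p = 0.00416 with an estimated correlation), with Abcc8 down 2.81-fold (98.6 ± 2.16 against 277 ± 2.96 CPM), Pcsk1 2.37-fold and Pdx1 1.62-fold. Some immediate early genes rose, Nr4a1 by 2.75-fold and Fos by 2.61-fold. In that list 14 rose, 1 fell and 3 did not pass (14 and 1 adjusted over the list alone, adjusted p = 1.56e-06, and adjusted p = 0.129 with an estimated correlation). In the neuronal list 3 rose, 3 fell and 3 did not pass (4 and 3 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.0989 with an estimated correlation), Nefm and Nefl falling 3.19-fold and 3.10-fold and Tubb3 rising 1.60-fold. 4878 genes passed, 2458 up and 2420 down, 702 by 2-fold or more. The difference from the activin B effect without ALK7, tested as an interaction, passed for 381 genes (171 up, 210 down). The ALK7 cells had dox and the vector cells did not, so it carries any effect of dox as well. It may also carry other differences between the 2 cell populations, described below for cells without ligand. The effect was higher with ALK7 for Cabp7 by 4.98 on the log2 scale, Irak2 by 2.34, Vim by 1.44, Tgif1, a SMAD corepressor, by 1.02 and Smad9 by 0.69 (SE 0.0694, adjusted p = 0.000306), and lower for Pgm5 (−3.59), Tmod1 (−2.23) and G6pc2 (−0.56). Levels without ligand differed for some of these. Tmod1 rose from 11.6 to 87.1 CPM with ALK7 and from 1.35 to 47.6 without it. Vim stood at 15.2 and 14.6 CPM with ALK7, and fell from 27.9 to 9.85 without it. The count was 240 without replicate 2 of the ALK7 group, 244 without replicate 1 of ALK7 with activin B and 239 without replicate 2 of vector with activin B. In the beta cell list none rose, 6 fell and 22 did not pass (1 and 10 adjusted over the list alone, adjusted p = 2.65e-07, and adjusted p = 0.00512 with an estimated correlation). Both activin B comparisons called 2679 genes in the same direction (1375 up, 1304 down, where independent lists would share 285 and 264) and 19 in opposite directions, with r = 0.62 and rho = 0.63 across genes.

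Without ligand, AJ cells with ALK7 and dox were compared with vector cells without dox, which differ in plasmid and in dox together. The 2 cell populations may also differ for other reasons. Vector cells of batch 2 were not tested against those of batch 1. A shift of this control that owes nothing to ALK7 or dox may therefore enter the values below. Batch 1 vector cells at 2 h of dox, scaled apart, read Mmp2 46.7, Spp1 16.7, Ttr 442 and Psmb8 16.2 CPM. Batch 2 vector cells read 6.31, 1.36, 1024 and 43.8 CPM, and the ALK7 cells 40.2, 9.41, 223 and 13.2. Much of these differences may thus lie in the batch 2 control. Egr1 lay otherwise, at 4.73, 8.37 and 31.5 CPM in the same order. Mmp2 was 6.37-fold (40.2 ± 1.41 against 6.31 ± 0.140 CPM) higher, Spp1 (osteopontin) 6.90-fold (9.41 ± 0.688 against 1.36 ± 0.0241 CPM), Egr1 3.75-fold, Pcsk1 2.74-fold and Bmp7 174-fold (13 ± 0.463 against 0.0673 ± 0.0592 CPM) higher, and Ttr 4.60-fold, Scml4 25.7-fold (0.909 ± 0.333 against 23.6 ± 0.839 CPM), Psmb8 3.33-fold and Resp18 2.00-fold lower. Hspa5 was higher by 1.43-fold and Ddit3 (CHOP) by 1.96-fold. In the chaperone list 16 rose, none fell and 3 did not pass, or 16 and 0 adjusted over the list alone (adjusted p = 1.84e-08, and adjusted p = 0.032 with an estimated correlation). In the interferon list none rose, 12 fell and 8 did not pass, or 0 and 12 adjusted over the list alone (adjusted p = 4.54e-07, and adjusted p = 0.00479 with an estimated correlation). 4319 genes passed (2150 up, 2169 down), 739 by 2-fold or more.

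**Figure D3:**
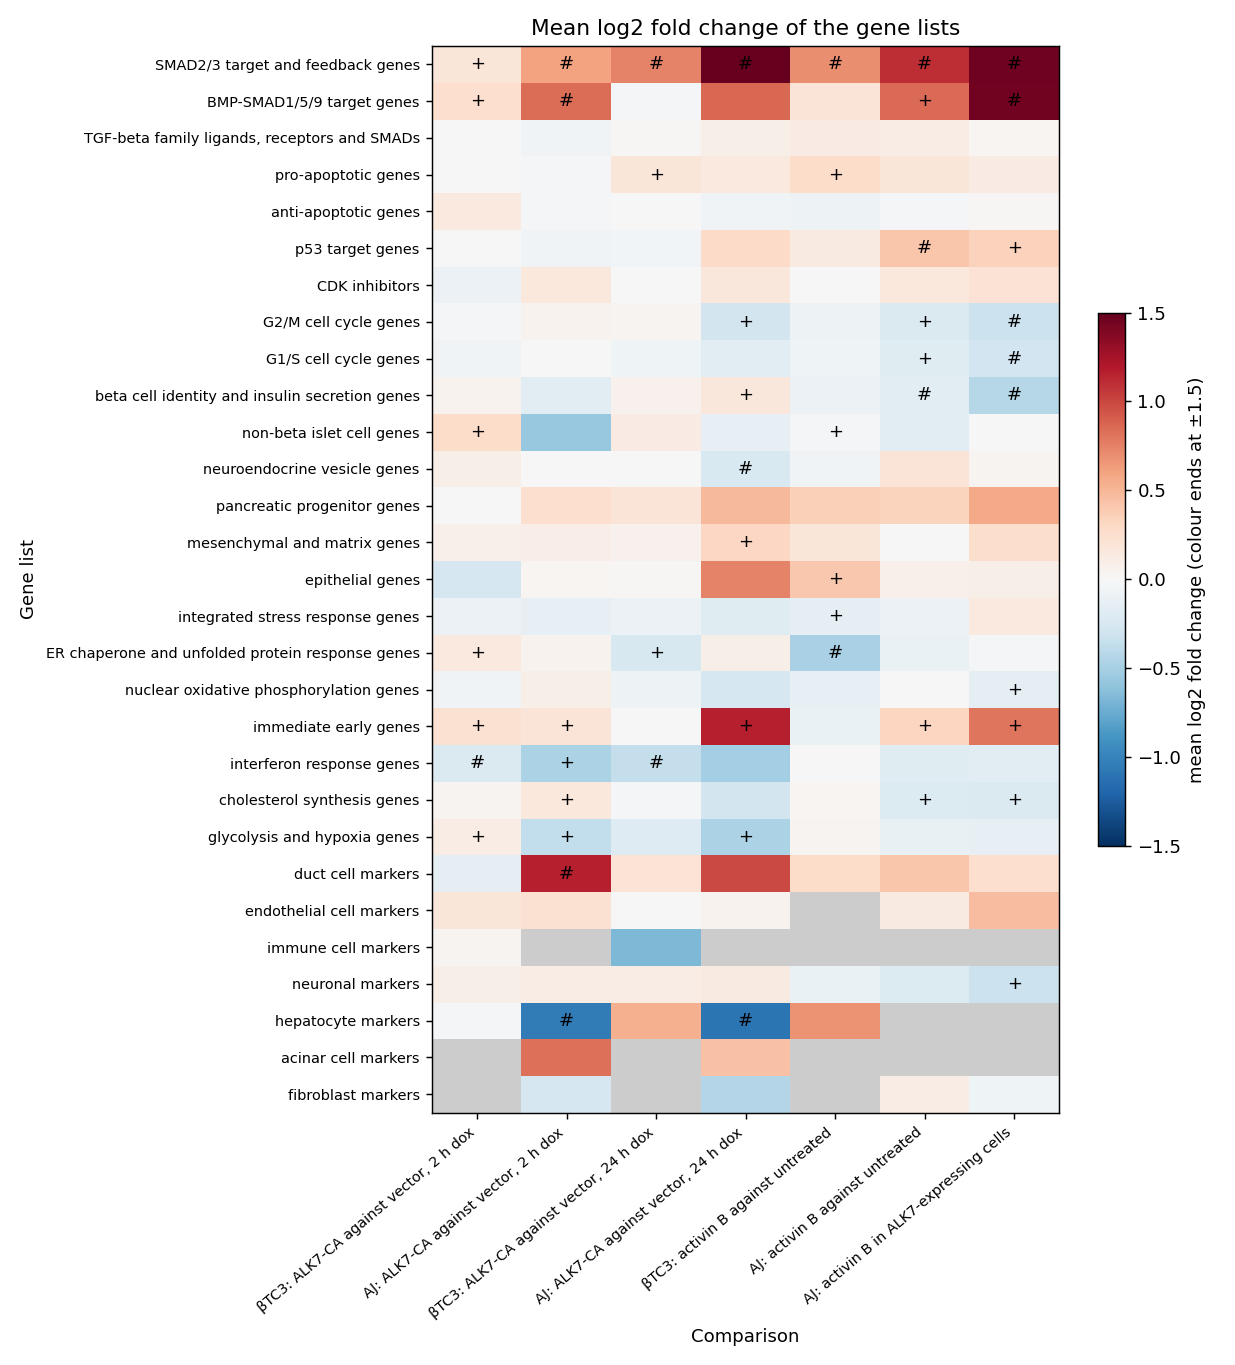
Mean log2 fold change over the measured members (colour, ending at ±1.5) of each gene list (vertical axis) in the 7 receptor and ligand comparisons (horizontal axis); grey marks a list not tested. A + marks a list past the adjusted threshold and a # one that also passed with an estimated correlation, 51 and 20 of 187 tests; the SMAD2/3 list passed upward in each of the 7.

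The lines were compared by testing the difference of their effects. At 24 h of ALK7-CA the effect was higher in AJ than in βTC3 for Ldlrad4 by 4.86 on the log2 scale (SE 0.197, adjusted p = 9.7e-08), Sox4 by 3.77, Atoh8 by 2.92 and Tgfb2 by 2.27, and lower for Glis3 (−2.23), Foxa2 (−1.36) and Sst (−3.04). In the SMAD2/3 list 12 rose, 2 fell and 11 did not pass (16 and 2 adjusted over the list alone, adjusted p = 9.85e-18, and adjusted p = 0.0114 with an estimated correlation). The difference passed for 2835 of 16194 genes (1348 up, 1487 down). Called in both lines in the same direction were 1147 genes (746 up, 401 down, against 236 and 146 for independent lists), and 185 in opposite directions, with r = 0.41 and rho = 0.37 across genes. With the replicate block 2381 were shared. For activin B the effect was higher in AJ for Sox4 by 1.53, Perp by 1.31 and Snap25 by 0.95, and lower for Acvr1c (−1.27), Bmf (−1.17), Abcc8 (−0.88) and the mechanically gated channel gene Piezo1 (−3.28). For Perp and Piezo1 the difference lay mainly in βTC3, where Perp fell from 29.8 to 15.5 CPM and Piezo1 rose from 1.34 to 13.5. In AJ they went from 1.37 to 1.80 and from 11.4 to 11.8 CPM. The chaperone list, which fell in βTC3, held 16 genes with a higher effect in AJ and none with a lower one (18 and 0 adjusted over the list alone, adjusted p = 5.85e-17, and adjusted p = 0.00493 with an estimated correlation). 1408 genes passed (712 up, 696 down), and 1198 were called in both lines in the same direction (761 up, 437 down, against 199 and 146; 139 opposite; r = 0.38 and rho = 0.36).

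ALK7-CA at 24 h and activin B were compared within each line and across batches, each against the controls of its own batch. A shift between batches cancels only where it is the same in treated and control cells. AJ vector cells read Ttr at 353 CPM with 24 h of dox in batch 1 and 1026 without dox in batch 2. For Ptprn2 they read 684 and 1116 CPM, and for Hspa5 721 and 695. Replicate 1 of AJ with ALK7-CA, where transcripts of βTC3 were read, enters the AJ values. In βTC3 the ALK7-CA effect was higher for Myom1 by 2.60 on the log2 scale, which was 5.16-fold higher already at 2 h, Adamtsl2 by 2.62, S100a4 by 1.86, Sox4 by 1.30, Gcg by 1.28 and Pmepa1 by 0.84 (SE 0.141, adjusted p = 0.0104), and lower for P2rx7 (−1.39) and Oasl2 (−0.80). 207 genes passed (165 up, 42 down), or 811 with the replicate block and 325 with DESeq2. The count was 132 without replicate 1 of ALK7-CA, 114 without replicate 1 of vector at 24 h and 133 without replicate 2 of activin B. The 2 treatments shared 1340 βTC3 calls in direction (844 up, 496 down, against 147 and 76.8; 14 opposite; r = 0.67 and rho = 0.60; 2519 with the block). In AJ the ALK7-CA effect was higher for Sox4 by 3.56, Bmf by 2.13 and Spsb1 by 1.94, and lower for Brinp3 (−5.38, with the rise of its control), Glis3 (−2.23, and 4.10-fold lower already at 2 h) and Scg2 (−0.98). In the vesicle list none rose, 8 fell and 12 did not pass (0 and 9 adjusted over the list alone, adjusted p = 1.45e-06, and adjusted p = 0.00511 with an estimated correlation). 2368 genes passed (1106 up, 1262 down), and 2206 calls were shared in direction (1167 up, 1039 down, against 353 and 330; 135 opposite; r = 0.54 and rho = 0.48).

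Dox alone was examined in vector cells. After 2 h against 0 h, 1 gene passed in βTC3 (471 genes at an unadjusted p under 0.05, 4 genes with DESeq2), and in AJ none did with edgeR (381 at an unadjusted p under 0.05, 1 with DESeq2). The βTC3 count was 3 without replicate 1 of 0 h or without replicate 3 of 2 h, and the AJ count 1 without replicate 2 of 0 h. In a fit of the βTC3 0 and 2 h groups alone, the edgeR count was 0. After 24 h, βTC3 vector cells differed from those at 0 h in 3674 genes (1675 up, 1999 down), 7165 with the replicate block and 2135 in a fit of these 2 groups alone. Fhl2 fell 9.05-fold (1.14 ± 0.135 against 10.4 ± 0.927 CPM), Slc16a6 5.56-fold (10.3 ± 0.658 against 57.2 ± 2.09 CPM), the stress genes Ddit3 and Atf3 3.19-fold and 2.44-fold and the interferon target Mx1 3.62-fold, and Nppa was 119-fold (21 to 4732) higher by its counting interval. Several chaperones rose, Hyou1 by 1.43-fold and Pdia6 by 1.43-fold. In that list 12 rose, none fell and 7 did not pass (14 and 0 adjusted over the list alone, adjusted p = 1.65e-07, and adjusted p = 0.157 with an estimated correlation). In AJ 419 genes passed (222 up, 197 down), with Brinp3 up 14.7-fold (4.97 ± 1.19 against 0.332 ± 0.107 CPM), Xkr4 up 5.90-fold (13.9 ± 3.86 against 2.35 ± 0.2501 CPM) and the tight junction gene Cldn15 down 4.45-fold (1.35 ± 0.0473 against 6.01 ± 0.0737 CPM). In the cholesterol synthesis list none rose, 6 fell and 15 did not pass, or 0 and 16 adjusted over the list alone (adjusted p = 9.54e-15, and adjusted p = 0.0018 with an estimated correlation). The AJ count was 168, 116 and 152 without replicates 1, 2 and 3 of 0 h, 124, 158 and 678 without replicates 1, 2 and 3 of 24 h, and 20 in a fit of these 2 groups alone. It was 818 with DESeq2 and 210 without the filter on low counts.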

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

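The tests in this part, the counts over other splits of the libraries included, were written down after the results were seen, and the single genes named here were chosen after their values were seen.

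Each of 5 differences between effects passed for many genes. The ALK7-CA effect at 24 h differed between AJ and βTC3 for 2835 genes and the activin B effect for 1408, the ALK7-CA effect differed between 2 and 24 h for 3246 genes in AJ and 924 in βTC3, and the activin B effect differed with and without ALK7 for 381. Among them, 182, 139, 221, 13 and 19 genes were called in opposite directions in the 2 effects compared. Those with a named symbol, a change of at least 2-fold in each direction and a mean log2 CPM of at least 2 are listed here. With ALK7-CA they were Ajap1, which differed between the lines by 4.27 on the log2 scale (2.71 in AJ, −1.56 in βTC3), then Hapln1, a link protein of the extracellular matrix (−3.31, with −1.56 in AJ and 1.75 in βTC3), Rgs4, a regulator of G protein signalling (−3.00, with −1.15 and 1.84), and Serpina1e (−2.99, with −1.95 and 1.03), whose reads are hard to tell from those of its paralogs. With dox alone βTC3 vector cells fell in Rgs4 and Serpina1e (−1.11 and −0.76), so the βTC3 values include a change of the control, and Serpina1e was lower in AJ already at 2 h. With activin B they were the acid-sensing channel gene Asic4 (2.35, with 1.23 in AJ and −1.12 in βTC3) and Rnf152 (−2.04, with −1.04 and 1.01). Between 2 and 24 h of ALK7-CA in AJ they were Amotl1 (3.90, with 2.45 at 24 h and −1.44 at 2 h) and Dok5 (3.34, with 2.26 and −1.08).

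Of 25 splits of the libraries, the number with as many genes as the real difference, the real split included, was 1 between the lines with ALK7-CA (2835, highest other 2825), 1 with activin B (1408, highest other 687) and 1 between ALK7-CA and activin B in βTC3 (207, highest other 116). It was 2 for the change from 2 to 24 h in βTC3 (924, highest other 962) and 3 in AJ (3246, highest other 3777), 3 for the activin B effect with and without ALK7 (381, highest other 1593) and 3 for ALK7-CA against activin B in AJ (2368, highest other 3225). The high values came from the 4 splits that kept 1 pair of groups as the labels have it or mirrored and so hold a real effect, and in the 20 that regrouped both pairs at most 1 gene passed. These ranks therefore say nothing on chance for any of the 7. The 1593 genes, several times the real 381, thus point to a structure of the samples, the activin B effect within the pair left as labelled.

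With 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real value and the highest of the other splits were, in βTC3, 241 and 0 for ALK7-CA at 2 h, 2134 and 0 at 24 h, 3210 and 1 for activin B, 3674 and 0 for 24 h of dox and 1 and 2 for 2 h of dox (3 splits as high, the real one included). In AJ they were 2443 and 0 for ALK7-CA at 2 h, 6305 and 0 at 24 h, 3348 and 2 for activin B, 4878 and 0 for activin B with ALK7, 4319 and 0 for ALK7 against vector, 419 and 1 for 24 h of dox and 0 and 1 for 2 h of dox (10 splits as high). In the βTC3 splits that part all 3 pairs, no gene passed. For gene lists, 1 of 10 joint splits gave as many as the real one (51, highest other 28), again too few. For each of the 7 counts of shared calls (1147, 1340, 2206, 1198, 2679, 153 and 1594), 1 of 100 pairs of splits, the real one, gave as many, and the highest other was 0. The other splits of each comparison call at most 2 genes, so this was settled beforehand and decides nothing.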

How the results depend on the processing

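Of 313 counts under an alternative, 242 lay within 1.5 times the reported one and 71 did not, 20 of these with 1 library left out. Of 3191 values of named genes, 3165 kept their direction and their side of the threshold, 10 kept the direction but no longer passed, 9 passed only under the alternative, 6 without a test moved and 1 reversed: Ins2 in AJ with ALK7-CA at 24 h, −1.95 on the log2 scale without replicate 1 of that group (−1.95 to 10.24 over the libraries left out, with adjusted p from 0.00512 to 0.613 over the alternatives). Where an alternative's own filter left out a gene, as DESeq2 did for Ins2 here, there is no value. The counts of lists and of shared calls without that library were chosen after seeing the data: 53 lists, and 1144 calls shared between the lines, 2033 between ALK7-CA and activin B in AJ and 1583 between 2 and 24 h in AJ. Where a count moved, the cause was not tested, except that asking also for a 2-fold change passes fewer genes by construction.

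An absolute log2 fold change of at least 1 left, in βTC3, 42 genes with ALK7-CA at 2 h, 503 at 24 h, 283 for the change between them, 0 and 468 for dox at 2 and 24 h and 405 with activin B. In AJ it left 558, 1715, 1046, 44 with dox at 24 h, 443 with activin B, 702 with activin B and ALK7, 739 for ALK7 against vector and 65 for the activin B effect with and without ALK7. Between the lines it left 1121 with ALK7-CA and 272 with activin B, and between ALK7-CA and activin B 59 in βTC3 and 783 in AJ. Shared calls with it in both comparisons were 188 between the lines with ALK7-CA and 92 with activin B, 206 and 290 between ALK7-CA and activin B in βTC3 and AJ, 298 with and without ALK7, and 24 and 342 between 2 and 24 h in βTC3 and AJ.

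The replicate block gave, in βTC3, 1136 genes with ALK7-CA at 2 h, 4410 at 24 h, 2553 for the change, 7165 with dox at 24 h and 811 for ALK7-CA against activin B. AJ was read as not paired, though 5 of 10 pairs of groups in its batch 1 passed the pairing bound. There the block gave 3895 with ALK7-CA at 2 h, 4954 for the change, 1603 with dox at 24 h and 623 for the activin B effect with and without ALK7. Shared calls with it were 2381 between the lines with ALK7-CA, 2519 between ALK7-CA and activin B in βTC3, and 538 and 2468 between 2 and 24 h in βTC3 and AJ. In AJ the block brought the neuronal list at 2 h (adjusted p = 0.0324) and, at 24 h, the BMP, G1/S, oxidative phosphorylation and cholesterol lists (0.0345, 0.0382, 0.0192 and 0.0177) past the threshold and ended the call of the mesenchymal list (0.0607). With those printed beside the βTC3 results at 2 h, it changed no other list call. The list tests with the block were made at the preset correlation only. Mki67 in AJ with ALK7-CA at 24 h passed with the block (−0.18 on the log2 scale).

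DESeq2 gave 365 genes with ALK7-CA at 2 h in βTC3, 4 and 1 with dox at 2 h in βTC3 and AJ, 818 with dox at 24 h in AJ and 325 for ALK7-CA against activin B in βTC3. Without the low-count filter 150 passed with ALK7-CA at 2 h in βTC3 and 210 with dox at 24 h in AJ. In fits of the compared groups alone, 31 passed with ALK7-CA at 2 h, 0 and 2135 with dox at 2 and 24 h in βTC3, and 20 with dox at 24 h in AJ. With an estimated correlation 20 lists passed and with fry 112.

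With each library left out in turn, the counts ran, in βTC3, from 77 to 208 with ALK7-CA at 2 h, 1619 to 1866 at 24 h, 641 to 806 for the change, 1 to 3 and 2504 to 3311 with dox at 2 and 24 h and 2174 to 3046 with activin B. In AJ they ran from 1726 to 2518, 5347 to 6477 and 2613 to 3514 for the same ALK7-CA results, 0 to 1 and 116 to 678 with dox, 2643 to 3144 with activin B, 3961 to 4406 with activin B and ALK7, 3556 to 3965 for ALK7 against vector and 239 to 363 for the activin B effect with and without ALK7. Between the lines they ran from 2285 to 3247 with ALK7-CA and 1010 to 1421 with activin B, and between ALK7-CA and activin B from 114 to 218 in βTC3 and 1802 to 3030 in AJ. Of simulated changes, those of 1.5-fold were found less often (22.4 to 76.1%) than those of 4-fold. Depth was not varied in these simulations.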

Other observations

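Several changes not given above were also seen. In AJ with ALK7-CA at 24 h the inhibitory SMAD gene Smad6 rose 16.1-fold (24.9 ± 5.39 against 1.54 ± 0.568 CPM), Hey1 4.47-fold and the ligand gene Tgfb2 3.78-fold, while Gdf11 fell 1.48-fold. The immunoproteasome gene Psmb8, 2.60-fold lower already at 2 h, fell 4.07-fold and the interferon target Usp18 2.71-fold. With activin B, Usp18 fell 3.29-fold in AJ vector cells and 3.48-fold in AJ cells with ALK7. The interferon target Oasl2 rose 4.38-fold (5.14 ± 0.415 against 1.17 ± 0.0555 CPM) in AJ with ALK7-CA at 24 h, 2.11-fold with activin B in AJ vector cells and 2.75-fold in AJ cells with ALK7. In the AJ interferon list with ALK7-CA at 24 h, 3 rose, 7 fell and 8 did not pass (3 and 7 adjusted over the list alone), and the list itself did not pass (adjusted p = 0.0666), though it did downward without replicate 1 of the ALK7-CA group (3 rose, 9 fell and 6 did not pass, adjusted p = 0.0102, and adjusted p = 0.0721 with an estimated correlation). With activin B in vector cells 1 rose, 4 fell and 15 did not pass (1 and 4 adjusted over the list alone), and the list itself did not pass (adjusted p = 0.23). In cells with ALK7 2 rose, 4 fell and 14 did not pass (3 and 5 adjusted over the list alone), and the list itself did not pass (adjusted p = 0.331). In βTC3 with ALK7-CA at 24 h, Ucn3, a marker of mature beta cells, rose 4.01-fold (0.859 ± 0.258 against 0.207 ± 0.0470 CPM), and Afp and Alb rose 2.84-fold and 2.29-fold.

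The tests below were all chosen after the results were seen. The bounds set on shares, on Y-linked genes and on abundance were also set afterwards.

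Transcripts of βTC3 were read in replicate 1 of the AJ ALK7-CA group at 24 h. Of 19 genes over 50 CPM in βTC3 and under 0.5 CPM in AJ, 100% lay within 2-fold of their median share of 6.35% (3.62 to 8.91%), with Npy at 66.7 and Igf2 at 320.1 CPM by total count, as RNA or reads of βTC3 cells mixed into this library would give. A first limit of 0.1 CPM left 7 genes with a median of 7.21% (4.57 to 7.53%). Expression of these genes by AJ cells with ALK7-CA was argued against by the other libraries of the group, at a median of at most 0.0572% (highest single gene 4.98%) over 19 genes chosen without any library of this group. A mixture is therefore the candidate explanation, and where it arose stays open.

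The 2 h difference between ALK7-CA and vector cells could come from cell populations that differed before dox was added, from a receptor response within 2 h or from activity of the construct before dox, and no value here decides between these. Y-linked genes were higher in each ALK7-CA library than in each vector library in 14 of 14 combinations, by 1.64 to 3.29-fold, but they were singled out for showing this, so it does not test whether populations differed. Of the AJ genes called at 2 h, 42.4% were also called as changing by 24 h (43.6% in βTC3), a share that does not bear on these explanations. Of the genes called at 2 h, 83.4% in βTC3 and 82.2% in AJ had the same direction at 24 h, and of 103 AJ genes lower by 4-fold or more at 2 h, 80 were still lower by 2-fold or more. ALK7-CA cells at 0 h, which were not analysed here, would set a response within 2 h apart from the other 2.

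βTC3 vector cells after 24 h of dox differed from those at 0 h in 3674 genes, against 419 in AJ vector cells. An effect of dox or of time in culture that both lines share was argued against by r = 0.0175 across 14484 genes, which are not independent replicates (rho = −0.0026), and by 72 of 179 genes called in both lines having the same direction. Of the 3674 genes, 402 (488 with the replicate block) changed by more than 1.56-fold, by over 2 SE. This was the highest ratio of 2 library totals between the groups, but fold changes were already scaled by library size. The ratio therefore sets no limit on them and does not test depth. The mean total count of the 24 h libraries was 1.18 times that of the 0 h libraries (SE 0.124). It was under a bound of 1.2 set before the ratio was seen, by less than its SE, and over a bound of 1.1 set afterwards. Of the 402 genes, 290 fell and 112 rose. A difference in total that is the same for all genes is taken out by the scaling. Whether depth had a part in another way, as at low counts, was not decided. An effect of dox or of time particular to βTC3 was not tested.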
